A study of Homo sapiens with 5 samples.

How the data were processed

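Gene expression was measured by RNA sequencing in 5 libraries of human macrophages derived from CD14-positive blood monocytes with 10 ng/mL M-CSF in medium with 10% serum: 1 untreated control and 1 library each after 1, 3, 6 and 24 h of 20 ng/mL TNF. The labels call the cells both monocytes and monocyte-derived macrophages; the protocol describes macrophages. How many donors gave the cells, and whether a library pools donors, is not given in the sources used here.

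The deposited table holds 1 value per gene symbol and library for 23682 symbols, of which 5087 are at 0 in all libraries, and its header names no unit. The values were taken as RPKM (reads or fragments per kilobase of gene length, scaled by library depth), because they are not whole, sum to 412659 in control, 438007 at 1 h, 420184 at 3 h, 436956 at 6 h and 416160 at 24 h, and are multiples of a step per gene that follows gene length. Per the submitters' processing notes the build was hg19 and the tools named were FastQC, Trim Galore, STAR 2.5.2b and DESeq2, without their roles; how reads were counted per gene, whether strand was used and how reads of near-identical genes were assigned is not given in the sources used here. Such choices decide the values of gene families such as metallothioneins and CCL3 and CCL4, and of overlapping genes such as SEPP1 and CCDC152. Symbols are printed as in the table, some of them older names: IL8 is CXCL8, SEPP1 is SELENOP. The annotation at hand was of another build, so no coordinates are given; GENCODE version 29 served only for gene and 3' UTR lengths and sequences.

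Depth was read back from the values. For 758 genes with a single annotated transcript, the smallest step between libraries was set against transcript length (Spearman correlation across genes -0.95); 326 of them shared a mode, which gave 55790000 reads for control, 56620000 for 1 h, 62400000 for 3 h, 67800000 for 6 h and 55680000 for 24 h. With these depths 13647 of 18595 detected genes (73.4%) came out as whole reads in all libraries, within 0.01 reads and searching up to 3000 reads. As a control, 1000 genes were drawn from those that came out whole with more than a few reads in each library. With the depth of the 3 h library wrong by 0.3%, 89 of them still came out whole. The sets of genes differ, so these rates cannot be compared directly. A higher limit of reads was tried first and lowered because it let more genes pass with wrong depths. The share of 73.4% was too low to replace the deposited values by reads, and the reads were used only to judge counting error. A gene of 1 kb at 1 RPKM has at least 55.7 reads at these depths, and at 5 RPKM 278.4 reads, a counting CV of 6.0%. Counting error covers neither differences between cultures or donors nor library preparation, which 1 library per condition cannot measure.

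The planned analysis assumed read counts scaled by TMM. As the table held RPKM, the form planned for that case was used: log2(RPKM + 1) of the values as deposited, without further scaling and without a counting interval. All log2 folds are on this scale, which understates the change of genes at low levels. A gene was called higher or lower when its log2 fold was at least 1 in size, a fold of 2, and the higher of the libraries had at least 5 RPKM. No p-value was computed for any gene, since genes are not replicates. Comparisons were 1, 3, 6 and 24 h against control and 24 h against 6 h. Induced genes were at least 4-fold above control with at least 10 RPKM at the peak; retention is the log2 fold at 24 h divided by that at the peak, under 0.25 for transient, at least 0.5 for sustained and otherwise intermediate. The peak is the highest of the 4 times sampled.

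Lists of genes (39) by function or cell type were fixed before the data were examined. A member counted as measured with at least 1 RPKM in any library. The median of a list is described by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. Genes named in the text follow a rule fixed in advance: the 12 highest and 10 lowest of each comparison with at least 10 RPKM in the higher library, up to 4 members of each list with the largest log2 folds at the time when the median of the list was largest, the 5 strongest genes of each class and peak time, and 18 landmark genes. Symbols that are only a locus, clone or small RNA are not named but stay in the counts. Some genes of the sex chromosomes that tell donors apart were left out of the analysis, which leaves 23581 symbols. Genes named outside this rule are said to be so, and a few genes that the rule names are not reported here.

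The procedures were tested on simulated data. Unchanged libraries gave 0 or 1 calls per comparison with counting error only, and 93, 80, 84, 92 and 89 calls (at 1, 3, 6 and 24 h against control and 24 h against 6 h) with an assumed biological CV of 0.2; the true CV is unknown. They gave 0 genes induced 4-fold in both cases. Known folds between control and 24 h were planted in 200 genes each, in simulated libraries of 23581 genes. All planted genes had at least 5 RPKM in control. With counting error only, 100.0% of those of 3-fold, 99.5% of 5-fold and 100.0% of 10-fold were called in the right direction. With that CV these were 86.0%, 98.5% and 99.0%. Genes that start below 5 RPKM, such as IL1B, were not tried, so their recovery is unknown. The alternatives tried were scaling to equal sums, median-of-ratios and upper-quartile factors, pseudocounts of 0.5 and 10, no minimum or one of 20 RPKM, folds of 1.5 and 4, other limits for induced genes, retention on the linear scale and leaving out the 1, 3 or 6 h library. Trimmed-mean factors, a counting interval and lists without gene families of shared reads were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.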

Results

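RNA sequencing measured gene expression in 5 libraries of human macrophages, grown from CD14-positive blood monocytes in 10 ng/mL M-CSF, the growth factor that turns monocytes into macrophages. One library came from untreated cells (the control) and 1 each from cells given 20 ng/mL tumor necrosis factor (TNF), an inflammatory cytokine, for 1, 3, 6 or 24 h. The series asks which genes induced by TNF return toward their starting level in macrophages and which stay high; the synovial fibroblasts and the BET inhibitor that it also concerns are not analysed here. There were no replicates, so no difference below was tested between conditions. Genes are called higher or lower by a rule of size: at least 2-fold on the log2(RPKM + 1) scale, with at least 5 RPKM in the higher library. The depth read back from the values was 55790000, 56620000, 62400000, 67800000 and 55680000 reads for control, 1, 3, 6 and 24 h, and 10802 to 11444 genes reached 1 RPKM. The median of all measured genes lay at log2 fold -0.24, -0.21, -0.16 and -0.10 at 1, 3, 6 and 24 h, so medians of gene lists are given relative to it.

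One hour of TNF went with cytokine, chemokine and NF-kB feedback transcripts at many times their control level. IL1B, the inflammatory cytokine interleukin-1 beta, stood at 2.61 RPKM in control and 1918 RPKM at 1 h, a log2 fold of 9.05 and the highest of the comparison. TNF itself stood at 2.59 and 228 RPKM (log2 fold 6.00), IL8 (CXCL8, which attracts neutrophils) at 42.0 and 3080 RPKM (6.16), and the receptor adaptor TRAF1 at 1.86 and 156 RPKM (5.77). CCL4 had a log2 fold of 7.79 and CCL3 of 5.99, both chemokines with near-identical gene copies: CCL4L1 and CCL4L2 (7.72 each) and CCL3L1 and CCL3L3 (6.03 each) cannot be told from them with certainty. Also among the 12 highest were PTX3, a secreted pattern-recognition protein (5.75), and the nuclear receptor NR4A1 (5.51). The lowest log2 folds were those of GIMAP7 (-3.99), FAM46A (-3.57), the metabolic kinase PDK4 (-3.51), FRAT2 (-3.42), the chemokine receptor CXCR4 (-3.24, from 202 to 20.4 RPKM), KLHL21 (-2.99), the transcription factor HHEX (-2.97), LPAR6 (-2.88), DUSP7 (-2.76) and the mRNA-binding protein ZFP36L2 (-2.73).

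Of 26 measured immediate-early genes, which are transcribed without new protein synthesis, 19 were higher at 1 h and 0 lower, with a list median 2.40 above that of all genes. Examples were NR4A1, the phosphatases DUSP2 (4.87) and DUSP5 (4.20) and the transcription factor ATF3 (4.25), while FOS was not past the rule (0.63). Of 19 NF-kB feedback inhibitors, 14 were higher and 0 lower (relative median 2.03), with IER3 at 4.34, TNFAIP3 at 3.87, NFKBID at 3.50 and NFKBIA, which holds NF-kB in the cytoplasm, at 3.13. Chemokines had 9 of 24 higher and 0 lower (1.84), cytokines 10 of 21 higher and 1 lower (1.26), cytokine signalling suppressors 9 of 19 higher and 1 lower (1.66), and adhesion and costimulation genes 7 of 19 higher and 0 lower (1.58), among them ICAM1 (4.00). Each of these 6 lists lay at percentile 100 of 10000 random lists. Interferon-stimulated genes did not share this: 0 of 40 were higher and 1 lower, with MX1 at -0.41. IL6, listed at 0 RPKM in the control, was at 5.58, 1.02, 0.54 and 0.09 RPKM at 1, 3, 6 and 24 h. By the 2-fold rule 355 genes were higher and 371 lower at 1 h. The higher share, 48.9%, depended on scaling: it was 40.1% with equal sums of RPKM, 72.1% with median-of-ratios factors, 68.9% with upper-quartile factors and 71.0% with trimmed-mean factors.

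**Figure D1:**
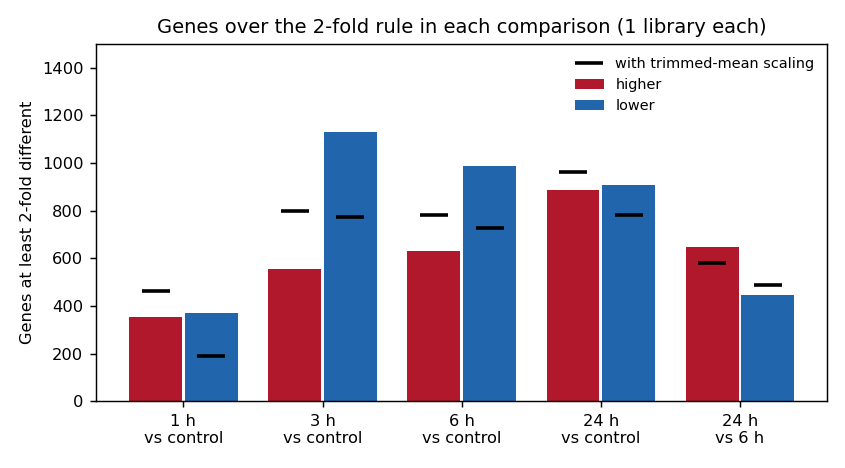
Number of genes at least 2-fold higher (red bars) or lower (blue bars) in each comparison of 2 single libraries, with black marks for the same counts after trimmed-mean scaling. As deposited, 355 genes were higher and 371 lower at 1 h, and 888 higher and 908 lower at 24 h; the marks stand apart from the bars most at 3 h.

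At 3 h the genes with the highest log2 fold were G0S2, a lipase inhibitor (6.95, from 1.34 to 288 RPKM), the costimulatory receptor TNFRSF4 (6.44), the adenosine receptor ADORA2A (5.92), IL1B (5.90), IL8 (5.85), the hyaluronan-binding TNFAIP6 (5.78), the interleukin-7 receptor IL7R (5.71), the cytokine subunit EBI3 (5.71), SGPP2 (5.69), CCL4 (5.54) and MSC (5.29). IL1B stood at 214 RPKM and TNF at 30.6 RPKM, both below their 1 h levels, whereas SOD2, the mitochondrial superoxide dismutase, went from 337 RPKM in control to 2752 at 1 h and 4727 at 3 h. The lowest log2 folds were those of YPEL3 (-4.30), SLC45A4 (-4.12), P2RY8 (-4.00), GPR34 (-3.87), the iron exporter SLC40A1 (-3.78), PIK3IP1 (-3.74), NUPR1 (-3.34), TESK2 (-3.25), ZNF395 (-3.18) and MGAT4A (-3.18). Of 26 immediate-early genes 6 were higher and 3 lower, with FOS at -1.89. Genes of the NRF2 and oxidative stress list had 7 of 16 members higher and 0 lower (relative median 1.13, percentile 100), with the cystine transporter SLC7A11 at 3.03, SRXN1 at 2.45, the glutathione synthesis subunit GCLM at 2.24 and OSGIN1 at 2.12. Chemokines had 13 of 24 higher and 0 lower (2.27), and adhesion and costimulation genes 12 of 19 higher and 2 lower (2.29). Of 20 NF-kB subunits and TNF receptor signalling genes 5 were higher and 0 lower (0.70), with NFKB1 at 2.93, NFKB2 at 2.24, IKBKE at 1.61 and RELB at 1.49. Of 25 markers of resting and alternatively activated macrophages 0 were higher and 11 lower (-0.78, percentile 0.0). In all, 554 genes were higher and 1132 lower, a higher share of 32.9%. That share came to 30.9% with equal sums, 58.3% with median-of-ratios, 50.5% with upper-quartile and 50.8% with trimmed-mean factors.

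At 6 h interferon-stimulated genes joined the higher group. Of 40 measured members 25 were higher and 0 lower, with a relative median of 1.68 (percentile 100), against 0.32 at 3 h with 4 higher and 3 lower. The antiviral gene MX1 stood at 14.8 RPKM in control, 23 at 3 h and 98.5 at 6 h (log2 fold 2.66), and the chemokine CXCL10 at 73.6 RPKM (5.61). Interferon-gamma type genes had 15 of 22 higher and 1 lower (1.94), among them IDO1, an enzyme of tryptophan breakdown, at 13.4 RPKM (3.71). The highest log2 folds of the comparison were those of TNFRSF4 (7.83, to 371 RPKM), EBI3 (7.75), G0S2 (7.75), TNFAIP6 (7.12), IL1B (6.93), IL8 (6.17), TNFRSF18 (6.02), MSC (5.93), CCL4 (5.89), ADORA2A (5.77), the gap junction gene GJB2 (5.69) and SGPP2 (5.68). Chemokines had 17 of 24 higher and 0 lower (3.35), with CCL2, which attracts monocytes, at 1074 RPKM (4.01). Adhesion and costimulation genes had 12 of 19 higher and 1 lower (2.58), with SLAMF7 at 4.54, TNFRSF9 at 4.42, CD40 at 4.24 and CD80 at 4.13. The lowest genes were SEPP1 (SELENOP, a secreted selenium carrier; -4.53, from 1666 to 71.3 RPKM) and CCDC152 (-4.64), which overlaps SEPP1 so that its value is uncertain. They were followed by GPR34 (-4.16), SLC40A1 (-4.09), AMICA1 (-3.99), SLC7A8 (-3.71), SLC18B1 (-3.66), MS4A6A (-3.64), DHRS9 (-3.58) and ZNF395 (-3.43). Resting and alternative activation markers had 17 of 25 lower and 0 higher (-1.26, percentile 0.0). The rule called 630 genes higher and 986 lower, 39.0% higher, against 33.5% with equal sums, 56.9% with median-of-ratios, 50.9% with upper-quartile and 51.8% with trimmed-mean factors.

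At 24 h metallothioneins, small proteins that bind zinc and copper, stood among the highest genes. MT1G stood at 1.58 RPKM in control and 2595 RPKM at 24 h (9.97), MT1H at 9.71, MT1M at 8.67 and MT2A at 8.53 (from 10.5 to 4243 RPKM); MT1L (8.03) and the other family members share near-identical sequence, so their single values are uncertain. Of 18 genes of metallothioneins and metal handling 13 were higher and 2 lower (relative median 4.07, percentile 100). Other genes among the highest were TNFAIP6 (9.15), IL1B (8.53, at 1328 RPKM), the neutrophil-attracting chemokine CXCL5 (8.47), IDO1 (8.36, at 362 RPKM), the autophagy gene MAP1LC3A (8.08), the chemokine CCL23 (7.49) and the sialic acid receptor SIGLEC10 (7.49). Cholesterol synthesis genes were higher together at this time: 22 of 23 measured members were higher and 0 lower (2.78, percentile 100), against 1 higher and 1 lower at 6 h. The epoxidase SQLE stood at 1.5 RPKM in control and 62.2 RPKM at 24 h (4.66), and the reductase DHCR7 at 0.28 and 27.1 RPKM (4.46). The culture time of the untreated library relative to the treated libraries is not given in the sources used here.

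Inflammatory and interferon lists also stood high at 24 h. Chemokines had 17 of 24 higher and 0 lower (3.46), with CCL8 at 5.95 and CCL5 at 5.51 (322 RPKM). Cytokines had 10 of 21 higher and 0 lower (1.29), with EBI3 at 5.76, IL1A at 3.81 and IL18 at 3.4. NF-kB feedback inhibitors had 12 of 19 higher and 1 lower (1.69), with TNFAIP3 at 185 RPKM (3.61) and NFKBIA at 1058 RPKM (2.91). Interferon-stimulated genes had 36 of 40 higher and 0 lower (2.06), with IFIT3 at 4.05, RSAD2 at 3.09, USP18 at 2.90 and MX1 at 2.33. Interferon-gamma type genes had 16 of 22 higher and 2 lower (2.20), with the checkpoint ligand CD274 at 4.01, GBP1 at 3.78 and APOL3 at 3.45. Among genes of MHC class I presentation 7 of 19 were higher and 0 lower (0.72), with PSME2 at 2.69, TAP2 at 2.12, TAPBP at 1.45 and NLRC5 at 1.39. Cytokine signalling suppressors had 11 of 19 higher and 1 lower (1.63), with SOCS3 at 4.19, HEY1 at 3.61 and IL1RN at 2.98. TNF stood at 9.90 RPKM (1.60), against 228 RPKM at 1 h.

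Markers of resting and alternatively activated macrophages and genes of MHC class II presentation stood low at 24 h. Of 25 resting and alternative activation markers 19 were lower and 0 higher (-2.44, percentile 0.0): SEPP1 was at 1666 RPKM in control and 1.25 RPKM at 24 h (-9.53), the coagulation factor F13A1 at -6.84, the ribonuclease RNASE1 at 2604 and 23.5 RPKM (-6.73), the folate receptor FOLR2 at -6.69 and the mannose receptor MRC1 at -5.96. The 10 lowest genes also held CCDC152 (-8.83, uncertain as above), MS4A6A (-7.17), HS3ST2 (-5.96), GPR34 (-5.71) and KCNJ5 (-5.66). Of 14 genes of MHC class II presentation 11 were lower and 1 higher (-1.23, percentile 0.0), with HLA-DMB at 612 and 46.5 RPKM (-3.69), HLA-DMA at -2.53 and the costimulatory ligand CD86 at -3.17, while the member that was higher was CD80 (3.49), the other ligand of CD28. At 6 h the same list had 2 lower and 1 higher (0.06). Of 24 lysosome and phagocytosis genes 9 were lower and 2 higher (-0.69), with ACP5 at -4.36, ATP6V0D2 at -3.90, HEXA at -2.22 and LIPA at -2.21. The lineage list as a whole kept no direction at 24 h, with 6 of 20 higher and 4 lower (0.18). By the rule 888 genes were higher and 908 lower at 24 h, 49.4% higher, against 48.8% with equal sums, 58.0% with median-of-ratios, 54.1% with upper-quartile and 55.1% with trimmed-mean factors.

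**Figure D2:**
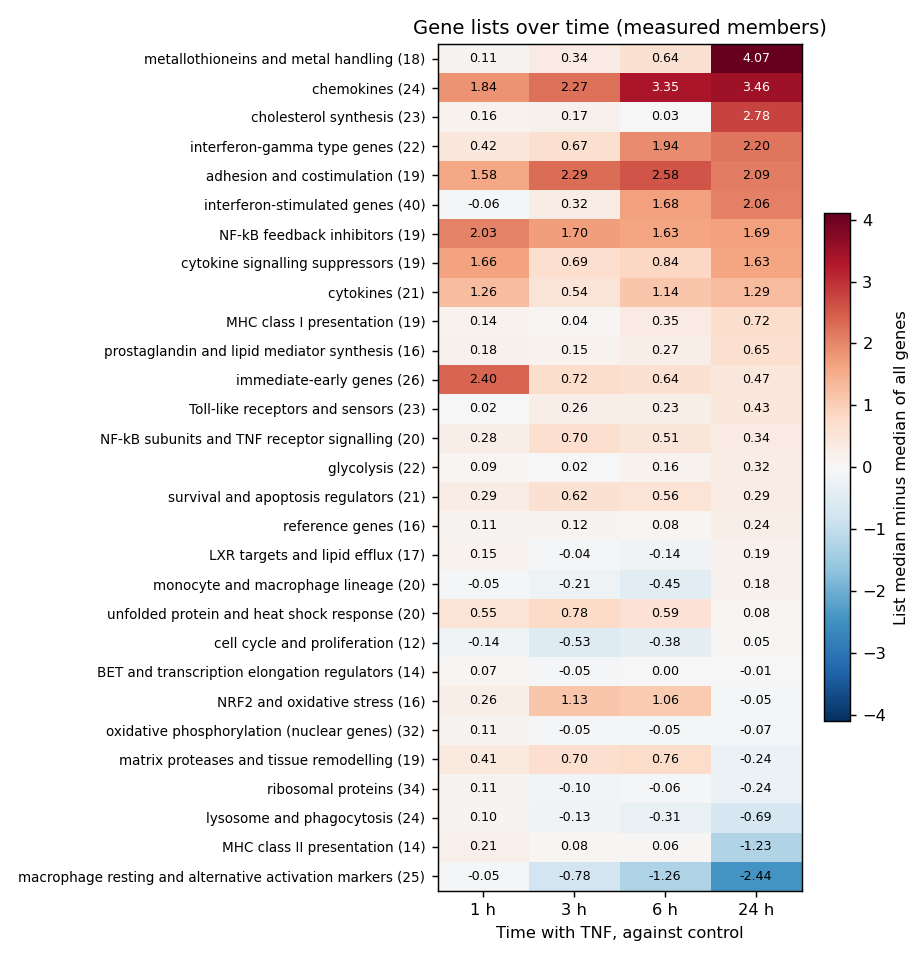
Median log2 fold over control of each fixed gene list with at least 10 measured members, minus the median of all measured genes, at 1, 3, 6 and 24 h of TNF (columns; the number of measured members is in parentheses and the color scale is log2). Immediate-early genes are highest at 1 h (2.40) and NRF2 genes at 3 h (1.13). The list of metallothioneins and metal handling (4.07) and cholesterol synthesis genes (2.78) are highest at 24 h, when resting macrophage markers are lowest (-2.44).

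The 24 h library was also set against the 6 h library, a comparison that does not use the control. Cholesterol synthesis genes were higher at 24 h for 21 of 23 members and lower for 0 (relative median 2.53, percentile 100), and of the metal handling list 12 of 18 were higher and 1 lower (2.90); without the metallothioneins the median of that list, not set against all genes, was -0.19. The highest log2 folds were those of MT1G (9.66), MT1H (9.29), MT1L (7.90), MT1M (7.51), the pseudogene MT1P2 (7.15), the chaperone CLU (6.91), MT1F (6.66), SIGLEC10 (6.61), the fatty acid desaturase FADS2 (6.34), MT2A (5.85), MT1X (5.77) and ENPP2 (5.69). FOLR2 (-5.62), SERPINB2 (-5.42, from 120 to 1.82 RPKM), SEPP1 (-5.01), RNASE1 (-4.93), CLEC10A (-4.33), CCDC152 (-4.19), EEPD1 (-4.00), ICOSLG (-3.95), F13A1 (-3.89) and KCNJ5 (-3.73) were lowest. MHC class II genes were lower for 12 of 14 members and higher for 0 (-1.64), resting and alternative activation markers lower for 15 of 25 and higher for 1 (-1.30), and NRF2 genes lower for 7 of 16 and higher for 0 (-1.0). Interferon-stimulated genes differed little in size between both times (0.25, percentile 99.9, with 3 of 40 higher and 1 lower). Inflammatory lists went in different directions. Chemokines had 6 of 24 higher and 5 lower (-0.69, percentile 0.0), and adhesion and costimulation genes 3 of 19 higher and 5 lower (-0.67, percentile 0.0). Cytokines had 4 of 21 higher and 2 lower (0.44, percentile 99.9). In total 648 genes were higher and 447 lower at 24 h, 59.2% higher, against 64.8% with equal sums, 52.3% with median-of-ratios, 53.5% with upper-quartile and 54.3% with trimmed-mean factors.

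**Figure D3:**
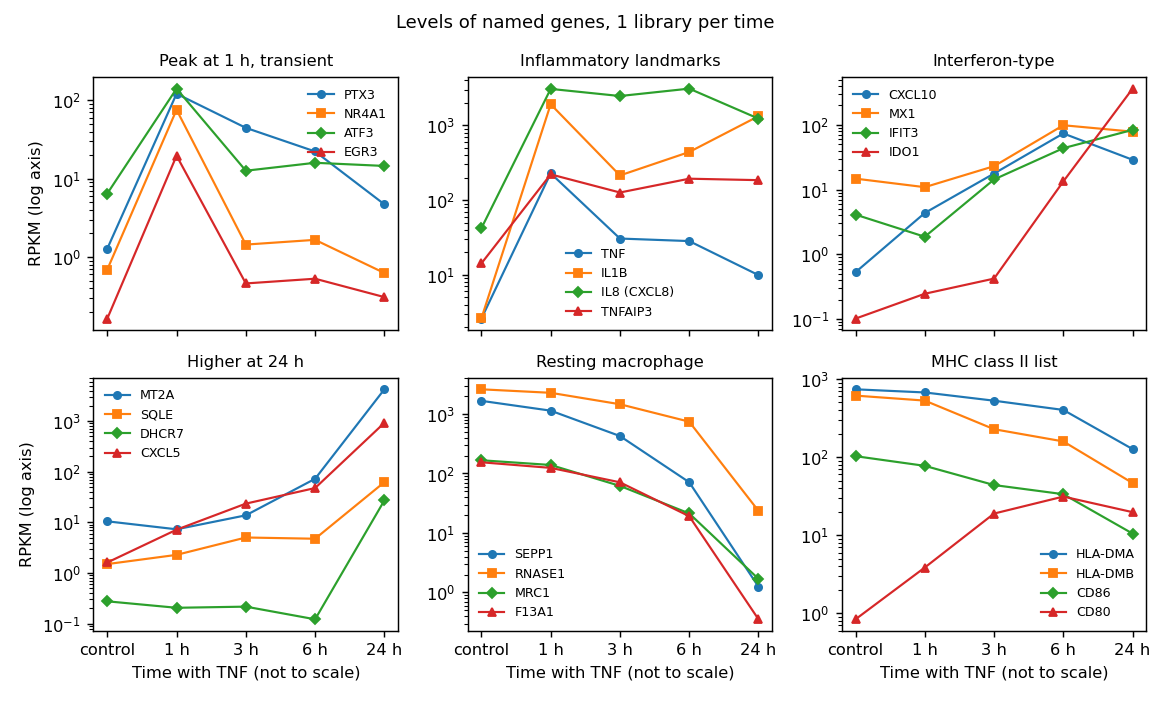
RPKM on a log axis of named genes in the control library and at 1, 3, 6 and 24 h of TNF (points, 1 library each, joined by lines; the time axis is not to scale). PTX3, NR4A1, ATF3 and EGR3 are highest at 1 h, IL1B is at 1918 RPKM at 1 h and 1328 RPKM at 24 h, MT2A reaches 4243 RPKM at 24 h, and SEPP1 goes from 1666 RPKM to 1.25 RPKM.

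To ask which induced genes came back toward control, genes at least 4-fold above control with at least 10 RPKM at their peak were sorted by their retention, the log2 fold at 24 h divided by that at the peak. Of 495 such genes 113 had their highest value at 1 h, 51 at 3 h, 76 at 6 h and 255 at 24 h, the last of which are sustained by construction. Of the 240 with an earlier peak 64 (26.7%) were transient, with a retention under 0.25, 41 (17.1%) were intermediate and 135 (56.2%) were sustained, with a retention of at least 0.5. Among genes with the peak at 1 h, 42 were transient, 26 intermediate and 45 sustained. At 3 h the numbers were 18, 10 and 23, and at 6 h they were 4, 5 and 67. Peak times rest on single libraries, and some are near ties, such as IL8 at 3080 RPKM at 1 h and 3106 RPKM at 6 h. A gene whose level held from 1 h on can count as a 6 h peak, so the contrast between peak times is partly built in. The transient class has no lower limit and also holds genes below control at 24 h, such as ICOSLG (-1.69) and OSGIN1 (-1.71).

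Transient genes with the peak at 1 h included PTX3 (log2 fold 5.75 at 1 h, 1.32 at 24 h, with a retention of 0.23), NR4A1 (5.51 and -0.06), MAFF (4.46 and 0.59), ATF3 (4.25 and 1.06, with a retention of 0.249 at the limit) and EGR3 (4.15 and 0.17), most of them transcription factors. With the peak at 3 h were AKAP2 (3.76 and 0.66, overlapped by PALM2-AKAP2), the transporter SLCO4A1 (3.29 and 0.42), the adhesion molecule ALCAM (3.27 and 0.55) and the reductase AKR1C1 (3.15 and -0.61), and with the peak at 6 h THBS1 (2.71 and -0.31), TIFAB (2.05 and -0.59) and thioredoxin, TXN (2.01 and 0.39), beside 1 small RNA symbol that is not named. Intermediate genes included TNF (6.00 and 1.60, with a retention of 0.27 close to the limit), the coagulation starter F3 (5.27 and 1.90), DUSP2 (4.87 and 1.59), ICAM1 (4.00 and 1.99), the potassium channel KCNN4 (4.09 and 1.86), FAM129A (4.57 and 2.25) and STEAP4 (3.92 and 1.54). Sustained genes included IL1B (9.05 and 8.53), whose level was lower in between, CCL4 (7.79 and 5.14), CCL3 (5.99 and 4.21), TNFAIP3 (3.87 and 3.61), ADORA2A (5.92 and 5.18), TNFRSF4 (7.83 and 5.58), EBI3 (7.75 and 5.76), G0S2 (7.75 and 6.68), IL8 (6.17 and 4.84), SOD2 (3.94 and 3.57) and NFKBIA (3.17 and 2.91). On the linear scale of retention 109 genes were transient, among them CCL4, TNFRSF4 and EBI3 of the sustained examples above. Sustained thus describes a ratio of log2 folds and does not mean that the level in RPKM held. Without the 1 h library, of the genes then induced, 26 were transient.

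**Figure D4:**
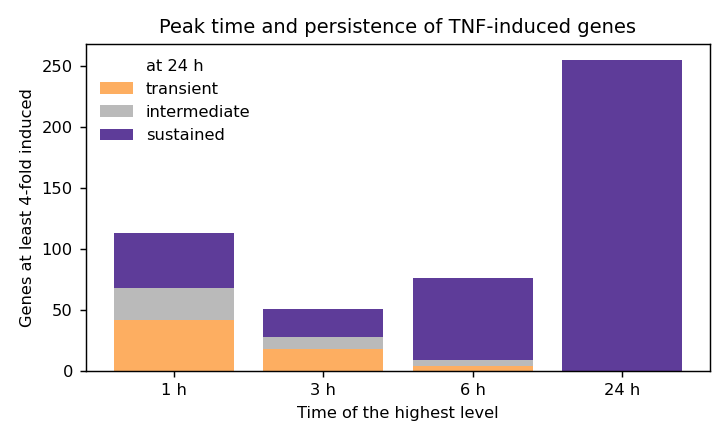
Number of genes at least 4-fold above control, by the time of their highest level (bars), divided by retention at 24 h into transient, intermediate and sustained. Of 113 genes with the peak at 1 h 42 are transient, whereas of 76 with the peak at 6 h 4 are. Peak times rest on single libraries and can be near ties, so this contrast is partly built in. The 255 genes with the peak at 24 h are sustained by construction.

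The genes past the rule at different times overlapped. Of the 355 genes higher at 1 h 182 were also higher at 24 h, where independent lists would share 35.0, and of the 630 higher at 6 h 433 were (62.1). Of the 986 genes lower at 6 h 567 were also lower at 24 h (99.4), and of the 371 lower at 1 h 101 were (37.4). All comparisons with control use the same library; simulated unchanged libraries with an assumed biological CV of 0.2 shared 10, 9, 1 and 0 genes in these cases, so part of the excess may come from the shared control, which could not be split. Opposite calls were rare, with 20 genes between 1 h and 24 h, 39 between 3 h and 24 h and 18 between 6 h and 24 h.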

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

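The tests of the share taken by induced genes, of scaling at 24 h, of metallothionein paralogs, of time in culture and of T and NK cells were chosen after the results were seen; that of gene length was not. The test of the share was first run with the induced genes left out of the median, and that of paralogs on MT1G alone; both were then widened to all genes concerned, and that of paralogs to all times. The test of scaling first took the median of each list minus that of all genes under each scaling, a difference from which a common factor drops out, and was replaced.

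The genes FCGR3B, ICOSLG, MT1F, OSGIN1, SERPINB2, VCAN and ZHX2, all named by the rule, stood above control at some times and below it at others, each by the 2-fold rule; the difference between times was not tested. ICOSLG, a costimulatory ligand, had log2 folds of 2.0, 2.32 and 2.27 at 1, 3 and 6 h and -1.69 at 24 h. SERPINB2, an inhibitor of plasminogen activators, had 1.31 at 1 h, 1.92 at 3 h and -4.83 at 24 h. OSGIN1 had 2.12 at 3 h, 1.00 at 6 h and -1.71 at 24 h. The metallothionein MT1F had -1.69 at 3 h and 6.96 at 24 h, and the proteoglycan VCAN had -1.57 at 3 h, -1.56 at 6 h and 3.37 at 24 h. FCGR3B, which has a near-identical copy, had -1.05 at 6 h and 1.28 at 24 h. The transcription factor ZHX2 had -1.05 at 1 h and 2.92, 1.2 and 1.29 at 3, 6 and 24 h. The lower values of these 2 genes depend on scaling: with median-of-ratios, upper-quartile and trimmed-mean factors FCGR3B was at -0.82, -0.91 and -0.90 at 6 h and ZHX2 at -0.81, -0.85 and -0.83 at 1 h, short of 2-fold, so their 2 directions are lost there. OSGIN1 at 6 h was at 0.92 with equal sums.

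Most expressed genes stood slightly lower at 1 h than in control, with a median log2 fold of -0.24 over 9004 genes as deposited; it was -0.32 with equal sums but 0.04, 0.0 and 0.03 with median-of-ratios, upper-quartile and trimmed-mean factors, which place most genes near 0 by construction, so the direction depends on scaling. A few induced genes taking a larger share of the values would lower all others: genes called higher held 15.3% of the RPKM sum at 1 h and 2.4% in control. After rescaling to equal sums of the genes not called higher the median was -0.13 (95% bootstrap interval over genes -0.14 to -0.12). These sums were of RPKM rather than reads, and genes that rose by less than 2-fold, such as ACTB (log2 fold 0.91), stayed in the reference. The test therefore cannot say how much of the shift this share accounts for. Gene length bias was tested in 3 classes of genes by length, and the median stayed below 0 in each, with -0.19 the highest of them. An effect of TNF on most genes and a difference between the cultures or their RNA remain open, and neither was tested.

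Metallothionein and cholesterol synthesis genes stood higher at 24 h. Scaling between libraries would move all genes alike, but the median log2 fold of all expressed genes was -0.08 and the smaller median of the 2 lists 2.69 (2.68 or more, with nothing subtracted, under the 4 other scalings), which argues against it. Reads of MT2A, the most abundant metallothionein, counted in its paralogs at a fixed share cannot exceed the lowest ratio of a paralog to MT2A. From times with at least 1 RPKM this allows 41.9% of the 24 h value for MT1F, 18.8% for MT1M, 4.96% for MT1G and 4.92% for MT1H. Upper limits from approximate reads were 63% or less, which argues against MT2A reads as the whole source for these 4 genes. Only MT2A was tried as a source. MT1G, at 2595 RPKM at 24 h, was not, so reads shared among the MT1 genes stay open, for MT1H as well. For MT1X a fixed share of MT2A allows 100% of the 24 h value, so shared reads and shared regulation cannot be told apart. The same 100% for MT1A and MT1E, both outside the naming rule, arose because times under 1 RPKM were left out. Some ratios there were lower: 0.0431 at 1 h for MT1E, against 0.0977 at 24 h, and 0.0 in control and at 6 h for MT1A. Those levels lie near the floor, so the test cannot decide for MT1A and MT1E. Time in culture or medium stays open as well, because there were 0 untreated libraries of another culture time, so an effect of TNF and one of time may both have contributed.

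IL7R, a marker of T cells, stood at 0.49 RPKM in control and 115 RPKM at 24 h, and NKG7, a marker of NK cells, at 2.04 and 141 RPKM. T or NK cells in the culture would bring their other abundant transcripts too. The highest of the other 20 markers of these cells at 24 h, GNLY, was at 1.73 RPKM and lower than its control level of 2.99, which argues against such cells as the source. Expression of both genes by the macrophages themselves is a hypothesis that these libraries suggest and that was not tested independently.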

How the results depend on the processing

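Results rest on 1 library per condition, so no setting measures the spread between cultures. Trimmed-mean factors, the counting interval and the lists without families of shared reads were chosen after the data were seen. No paired analysis was possible because each condition has 1 library and no test was run. The count of genes called in each comparison stayed within 1.5 times with each scaling, with a pseudocount of 0.5 and without a minimum. It also did so with a counting interval, which kept all 726 calls at 1 h. That interval could hardly have removed a call, so it says little about stability. Genes whose reads could not be read back were kept, and a 1 kb gene at 5 RPKM has a counting CV of only 6.0%. At 1, 3, 6 and 24 h against control and 24 h against 6 h, in that order, 726, 1686, 1616, 1796 and 1095 genes were called. With a pseudocount of 10 there were 289, 575, 666, 928 and 432, with a minimum of 20 RPKM 369, 816, 860, 1058 and 584, with a fold of 1.5 there were 1958, 3458, 3089, 2984 and 2378, and with a fold of 4 there were 202, 345, 451, 728 and 276. These follow from stricter or looser limits. The share of higher genes moved too: at 1 h, 48.9% by the main rule, it was 79.9% with that pseudocount, 69.4% with that minimum, 28.5% with a fold of 1.5 and 83.7% with a fold of 4. At 3, 6 and 24 h against control higher genes were fewer than lower ones by the main rule but more with a fold of 4 (52.2%, 54.8% and 53.7%), as they were with a pseudocount of 10 at 6 and 24 h (52.9% and 54.8%) and with a minimum of 20 RPKM at 24 h (53.9%).

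Of 495 induced genes, 64 transient, 41 intermediate, 390 sustained and 255 with the peak at 24 h, a pseudocount of 10 left 238, with 33, 15, 190 and 120. A peak minimum of 50 RPKM left 289, with 41, 25, 223 and 133. A 2-fold induction limit gave 1136, with 227, 102, 807 and 553, and an 8-fold limit 261, with 24, 15, 222 and 139. Median-of-ratios factors gave 64 intermediate genes, and the cause was not tested. Retention on the linear scale gave 109 transient genes, by its construction. Without the 1 h library there were 26 transient and 21 intermediate genes. Some genes with the peak at 1 h dropped out, and others were classed by a later, lower peak. TNF (3.14 at 3 h and 1.60 at 24 h) and ICAM1 (2.68 at 6 h and 1.99 at 24 h) then counted as sustained instead of intermediate.

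Of 332 values of named genes, each in the comparison for which it was chosen, 279 were at least 2-fold. Of these 279, 4 came under 2-fold with a scaling (NDUFS3, MCM4 and MCM7 at 3 h and CEBPA at 6 h) and 31 with a pseudocount of 10. Among the 279, 0 changed sign, but that was fixed in advance and says nothing about stability. The largest log2 difference of a scaling factor from control was -0.31, at 3 h with median-of-ratios factors, and a pseudocount cannot change a sign. Of the 53 smaller values 5 changed sign (GAPDH at 1, 3 and 6 h, TNFAIP3 and ACTB at 24 h against 6 h). Values in other comparisons, such as those of BRD3, FCGR3B and OSGIN1 at 6 h and ZHX2 at 1 h that came under 2-fold, are not among the 332. Of 190 list medians, 47 were at least 2-fold. Of these 25 came under 2-fold somewhere, most with a pseudocount of 10, which weighs down lists of genes at low levels, and 1 reversed: metallothioneins and metal handling at 24 h against 6 h, at -0.186 without the families of shared reads, as the metallothioneins carry it. Of the smaller medians 57 changed sign under some alternative. Low levels limit what can be read: folds of genes near 1 RPKM are understated by the pseudocount.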

Other observations

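The tests of AU-rich elements and of gene span were set before their results were seen; that of 3' UTR length was added after.

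Lists that the comparisons above do not describe differed from control in several directions. Prostaglandin and lipid mediator genes had 6 of 16 members higher and 0 lower at 24 h (relative median 0.65), with the prostaglandin E synthase PTGES listed at 0 in control and at 142 RPKM at 24 h, PTGS2 at a log2 fold of 2.76, PTGER4 at 2.11 and PTGIR at 2.01. Matrix protease and tissue remodelling genes had 4 of 19 higher and 2 lower at 6 h (0.76), with MMP9 at 2.79, PLAUR at 2.32, MMP14 at 2.24 and MMP19 at 2.23, and 6 higher and 6 lower at 24 h (-0.24). Survival and apoptosis regulators had 5 of 21 higher and 1 lower at 3 h (0.62), with BCL2A1 at 3.54, BIRC3 at 2.40, BID at 2.12 and BCL2 at 1.81. Toll-like receptors and sensors split at 24 h, with 7 of 23 higher and 5 lower (0.43): IRAK2 at 2.98 and CASP5 at 2.92, against TLR7 at -3.53 and the inflammasome adaptor PYCARD at -2.73. Of 17 LXR target and lipid efflux genes 1, the receptor NR1H3 (2.29), was higher at 6 h and 0 lower (-0.14), while 5 were higher and 3 lower at 24 h (0.19). Unfolded protein and heat shock genes had 4 of 20 higher and 0 lower at 3 h (0.78), namely DDIT4 at 1.31, DNAJB9 at 1.26, SDF2L1 at 1.13 and HSPA5 at 1.05. Of 12 cell cycle genes 3 were lower and 0 higher at 3 h (-0.53), with MCM6 at -1.60, MCM5 at -1.51 and MCM7 at -1.13, the last at -0.86 with median-of-ratios factors.

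Metabolic, ribosomal and transcription lists differed little from control. Glycolysis genes had 3 of 22 higher and 0 lower at 24 h (0.32), with HK2 at 1.78, SLC2A3 at 1.58 and SLC16A3 at 1.12. Nuclear genes of oxidative phosphorylation had 1 of 32 lower and 0 higher at 3 h (-0.05), NDUFS3 at -1.02 (-0.72 with median-of-ratios factors), and of 34 ribosomal protein genes 0 were past the rule at any time. Mitochondrially encoded genes had 0 measured members in the table. Of 14 BET and transcription elongation regulators 1 was lower at 1, 3 and 6 h, BRD3, a BET protein that binds acetylated chromatin, with log2 folds of -1.42, -1.65 and -1.10. The value at 6 h was -0.89 with median-of-ratios, -0.97 with upper-quartile and -0.96 with trimmed-mean factors, short of 2-fold. At 24 h BRD3 was at -0.24, and another member was the 1 of 14 that was lower. Of 16 reference genes often used for normalization 1 was lower and 0 higher at 24 h (0.24), GUSB at -1.55, and ACTB stood at 2680 RPKM in control and 5027, 5039, 5229 and 5152 RPKM at 1, 3, 6 and 24 h, log2 folds of 0.91 to 0.96. The monocyte and macrophage lineage list had 2 of 20 higher and 6 lower at 6 h (-0.45), with CD14 at 1105 and 349 RPKM (-1.66) and CEBPA at -1.22, which was -0.98 with median-of-ratios factors.

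Summed levels of markers of other cell types were low beside the 18466 RPKM of the 20 lineage genes in control. From control to 24 h the sum of B cell markers went from 11.2 to 1.6 RPKM, red blood cell markers from 5.3 to 0.6, platelet markers from 3.8 to 13.1, fibroblast markers from 0.6 to 5.2 and endothelial markers from 50 to 13.1, most of it PECAM1, which macrophages also express. Neutrophil markers went from 95 to 147.0 RPKM, with S100A12 at 60.3 and FCGR3B at 42.4 RPKM at 24 h. Of 3 measured neutrophil markers these 2 were higher, while 1 stood below control without passing the rule. T and NK cell markers went from 4.2 to 116.6 and from 9.1 to 145.2 through IL7R and NKG7. Dendritic cell markers went from 107.2 to 400.6 RPKM through IDO1, and from 107.1 to 38.8 RPKM without it, with 4 of 7 measured members higher and 1 lower at 24 h: IDO1, LAMP3 (3.79) and CCR7 (2.98) were among the higher and CLEC10A (-5.20) lower.

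AU-rich elements in the 3' UTR, which speed mRNA decay, were a candidate explanation for why some early genes returned toward control or below it and others did not. Among genes with the peak at 1 or 3 h, 34 of 54 transient genes with an annotated 3' UTR (63.0%) held at least 1 such motif, against 47 of 63 sustained genes (74.6%). The difference of -11.6 points (95% bootstrap interval -28.6 to 5.3; two-sided permutation p = 0.2285, across genes, which are not independent replicates) does not have the sign that the hypothesis needs, and its interval leaves a small difference in the other direction open. Lengths of the 3' UTR differed by 0.05 on the log10 scale (permutation p = 0.6807). Of all genes reaching 10 RPKM 43.7% held a motif.

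Length of the transcribed gene may bear on when a gene peaks, since a longer gene takes longer to transcribe. The median genomic span was 12.8 kb for 109 genes with the peak at 1 h and 24.4 kb for 240 genes with the peak at 24 h, a difference of -0.28 on the log10 scale (two-sided permutation p = 0.0002, across genes). The order was not steady over time, as 48 genes with the peak at 3 h had 58.3 kb and 71 with the peak at 6 h had 20.7 kb. The short span at 1 h therefore has the direction that the hypothesis needs, but a difference in span cannot show that transcription time set the peak. Transcription time alone would not give the order of the later times.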
